A study of Homo sapiens with 6 samples.

How the data were processed

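RNA from 6 cultures of the U266 line was hybridised to 6 one-colour (Cy3) Agilent gene expression arrays, 1 for each combination of construct (none, Scr, shKDM3A) and oxygen level (21% and 1%). Per the labels, the cells grew in serum-supplemented medium and total RNA was extracted with a phenol-based reagent. The duration of hypoxia is not given in the sources used here. All 6 arrays lay on 1 slide with 1 scan date. The normoxia arrays filled slide row 1 and the hypoxia arrays row 2, and each construct filled 1 column.

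Spot intensity values were made by the authors with Agilent Feature Extraction 11.5.1.1, per the file headers, which subtracted background and removed spatial trends within each array. The deposited intensity values are linear, background-subtracted and not normalized between arrays. The files also hold median spot and local background intensity, per the file headers. A deposited table of log2 values was set against the spot intensities. Its columns correlated across genes with log2 intensity minus the probe's median over the arrays (Pearson's r 0.934 to 0.977), so its direction is that of the signal and its values are centred per probe, while the exact shift and baseline remain unknown. Its array medians were 0.026, 0.040 and 0.017 in normoxia and -0.013, -0.010 and -0.062 in hypoxia, for untransduced, Scr and shKDM3A cells. Each array held 62976 spots, 58717 of them not controls, and 0 were saturated. Control spots and spots the software marked as outliers were left out, and spots of 1 probe were averaged. Of 50599 probes, 3 had every spot marked on some array, which left 50596. The 75th percentile of the signal was 630.9 to 732.8 on the normoxia arrays and 497.7 to 565.0 on the hypoxia arrays.

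The files pair probes with accessions only, so gene symbols were taken from a RefSeq gene table of assembly GRCh38.p14. Of the probes, 29032 had 1 symbol, 0 had several and 21564 had none; the symbols were 20991 different ones. The array design refers to another assembly (hg19), so no coordinates are given. Probes without a symbol were tested and counted but not named.

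The main values were log2 of the processed signal minus each array's 75th percentile. A gene was tested where its probe was well above background on at least 2 of the 6 arrays, and the probe with the highest mean signal stood for the gene. That left 31771 genes, 18042 of them with a symbol, and 25721 were seen on every array. limma 3.58.1 in R 4.3.3 was fitted with construct and oxygen as additive factors, which leaves 2 residual degrees of freedom. Contrasts were hypoxia minus normoxia, shKDM3A minus Scr and Scr minus untransduced. A second model added a different hypoxia response in shKDM3A cells and left 1 residual degree of freedom. P-values were adjusted by the Benjamini-Hochberg method, with a threshold of 0.05. Since 1 culture stands behind each array, the p-values measure only what the additive model leaves unexplained among these arrays. The overlap of genes raised by hypoxia and lowered by the knockdown was a count by size, at least 2-fold against both controls, and is not a test. Fisher's exact tests of it were added after the data were seen and treat genes as independent. For a gene above background on every array of one side and on none of the other, the fold is a lower bound against, on each dim array, the higher of the lowest signal above background and the probe's own. Python 3.11.15 with pandas 2.3.3, numpy 2.4.6 and matplotlib 3.10.9 read the files and drew the figures.

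Gene lists were fixed before the data were examined. The 27 lists cover HIF targets, glycolysis, JmjC demethylases, oxidative phosphorylation, the tricarboxylic acid cycle, the unfolded protein response and the ATF4 response. They also cover plasma cell genes, BCL2 family genes, cell cycle, interferon, NF-kB and p53 genes, sterol synthesis, and collagen and matrix. Further lists hold ribosomal proteins, ribosome biogenesis, MHC class I and class II, histones, autophagy and lysosome, and long noncoding RNAs (labelled nuclear-retained). The rest are markers of T and NK cells, monocytes and macrophages, epithelium and fibroblasts, mature B cells, and erythroid cells and megakaryocytes. All 27 lists were tested with camera at a preset correlation of 0.01, with an estimated correlation, and with fry. Fry tests whether a list's genes move on balance one way and does not compare them with other genes. With an estimated correlation camera rests on the 2 residual degrees of freedom of the fit, so few lists can pass and a failure says little.

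Named genes were taken by a rule fixed before the data were examined. They are KDM3A, MALAT1, NEAT1, HIF1A, KLF2 and IRF4, then the 10 higher and 10 lower genes per comparison with the largest smallest difference over the pairs of arrays (3 for the vector and 5 for the interaction), up to 5 genes per direction with a lower bound, and from each list up to 4 members with the largest difference and those that moved against the list. Genes with no symbol or only a provisional one, and sex-linked marker genes, were counted and not named, and values of some single list members are not reported here. The calculations were tested on simulated arrays of the 31771 genes with known changes. With 200 changed genes, the median estimates for the comparison with Scr were 1.00 and 1.99 for true log2 changes of 1 and 2, and 0% were called, while 89% and 98% had an unadjusted p under 0.05. With 6000 changed genes, hypoxia calls were 81.8% and 94.8% and Scr against untransduced calls 73.7% and 91.8% at the same sizes. In a simulated hypoxia comparison camera called the 1 list that was shifted and 0 of 27 others. The simulated genes varied independently, while the estimated correlation in the data reached 0.939 for the cell cycle list. The 0 therefore says nothing on false calls of lists whose genes move together.

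Alternatives set before the data were examined were quantile normalization, scaling to the median of bright probes, no filter and a strict filter on dim probes, the mean of a gene's probes, the deposited log2 table, leaving out each array and each construct pair, a model without construct, a trended and robust spread, other controls, other overlap rules and other list tests. Normexp background correction was planned on the mean signal, which the files used here lack as a column, and was run on the median signal with an offset of 50. That version and scaling to 8 spike-in probes were chosen after the data were seen.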

Results

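Gene expression was measured on 6 one-colour Agilent arrays of U266, an established human multiple myeloma (plasma cell tumour) line. The cells were of 3 kinds, namely cells with no hairpin per the labels (untransduced), cells transduced with a scrambled control hairpin (Scr), and cells transduced with a short hairpin RNA against KDM3A (shKDM3A). KDM3A is a JmjC-domain histone demethylase and a known target of hypoxia-inducible factor (HIF). Each kind was cultured in normoxia (21% oxygen) and in hypoxia (1% oxygen), with 1 array in each of the 6 groups. No group had a replicate, so every error below is the standard error (SE) of a model over all 6 arrays, whose spread is what construct and oxygen together leave unexplained. It includes no variation between repeated cultures. The share of probes well above background was 74.3% to 76.5% on the normoxia arrays and 66.8% to 72.1% on the hypoxia arrays. The number of arrays limits the precision of every value. All values are log2 signals relative to the array's 75th percentile, and differences are log2 differences unless called folds.

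The targeted gene was examined first. KDM3A was lower in the shKDM3A cells than in both controls at both oxygen levels, and it rose in hypoxia in each kind of cell. In normoxia its level was -0.55 in untransduced cells, -0.27 in Scr cells and -1.42 in shKDM3A cells. In hypoxia the levels were 0.78, 1.21 and -0.08. The difference between shKDM3A and Scr cells was -1.22 (SE 0.10), a 2.32-fold lower signal, and the difference from untransduced cells was -0.86 (SE 0.10). Adjusted over all genes tested, the limma p of the comparison with Scr was 0.466, and with a trended, robust estimate of the spread it was 0.00879. Hypoxia raised KDM3A by 1.39 (SE 0.08, limma adjusted p = 0.0236), or 2.61-fold. The size of the hypoxia response was 1.34 in untransduced, 1.48 in Scr and 1.34 in shKDM3A cells.

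**Figure D1:**
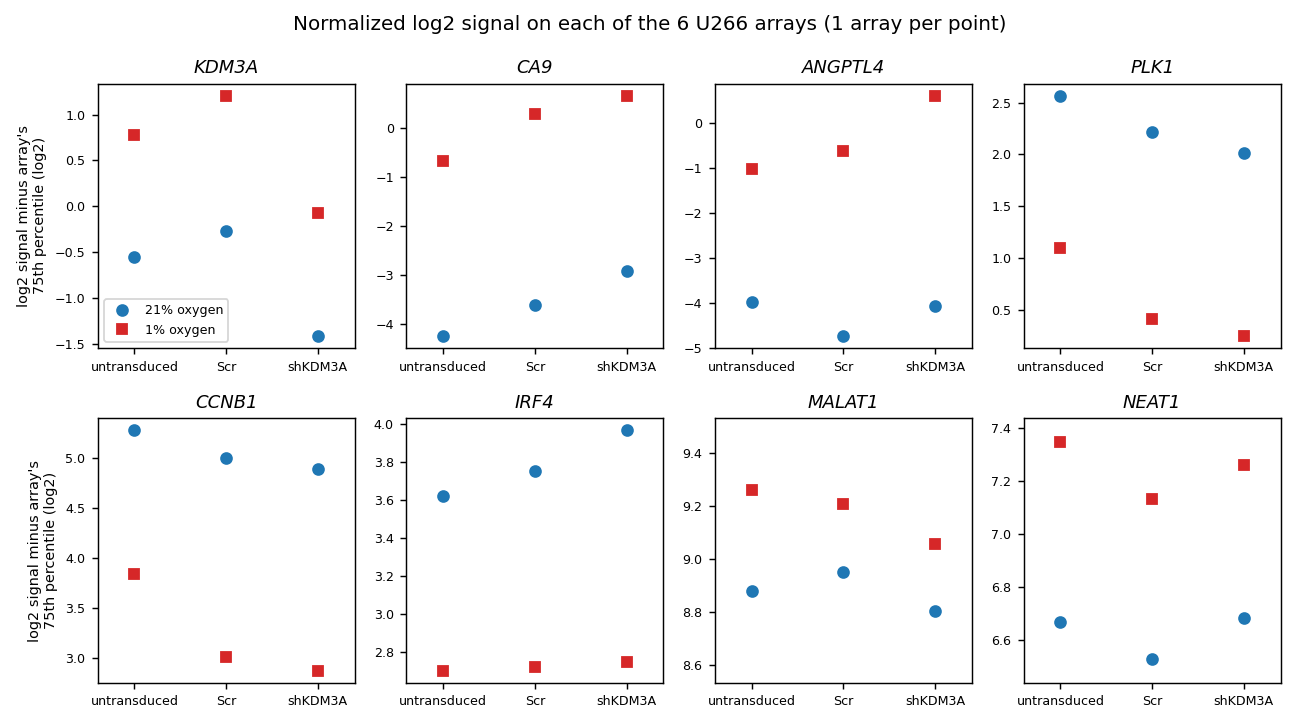
Normalized log2 signal (log2 signal minus the array's 75th percentile, vertical axis) of 8 genes in untransduced, Scr and shKDM3A cells, with 1 array per point, circles for 21% and squares for 1% oxygen; the vertical scale differs between genes. KDM3A lay at -1.42 and -0.08 in the shKDM3A cells, below both controls at the same oxygen level, while CA9 and ANGPTL4 were higher and PLK1, CCNB1 and IRF4 lower in hypoxia in all 3 kinds of cells.

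The first comparison asked which genes respond to hypoxia. The genes with the largest smallest difference over the 3 kinds of cells included CA9, a pH-regulating carbonic anhydrase, which rose by 3.67 (SE 0.10, 12.7-fold), and ANGPTL4, an inhibitor of lipoprotein lipase, which rose by 3.91 (SE 0.38). The metallothionein gene MT1H rose by 3.35 (SE 0.13) and the receptor tyrosine kinase gene FGFR3 by 2.73 (SE 0.09). The noncoding RNA UCA1 rose by 2.99 (SE 0.10), and SLC2A1-DT, a noncoding transcript divergent from the glucose transporter gene SLC2A1, by 3.27 (SE 0.25). MICALL2 (3.05), MYO15A (2.93), the potassium channel gene KCNQ1 (3.08) and BICDL2 (3.24) completed the 10 genes taken by the naming rule, and all 10 had an limma adjusted p of 0.0236. Among the 10 genes that fell, PLK1 (-1.68, SE 0.11) and CCNB1 (-1.82, SE 0.16) encode a kinase and a cyclin of mitosis, and DNAJB11 (-1.64, SE 0.11) encodes a chaperone of the endoplasmic reticulum. IL12A, a cytokine subunit gene, fell by 2.26 (SE 0.29, limma adjusted p = 0.026). TAF9B (-1.95), CKMT1A (-1.60), the histone gene H2AC16 (-1.94), CCNJ (-1.61), ARHGAP11A (-1.75) and PDE4DIP (-2.44) fell as well, each at an limma adjusted p of 0.0236. The 12 probes for PDE4DIP disagreed, with differences from -2.44 to 0.60, and with the mean of its probes it no longer passed (-0.54, limma adjusted p = 0.0731). The sizes of 8 of these genes shrank by over 1.5 times with normexp background correction, an alternative chosen after the data were seen, although all 8 still passed. They became 2.43 for CA9, 2.35 for ANGPTL4, 1.67 for FGFR3, 1.76 for SLC2A1-DT, 1.56 for MYO15A, -0.75 for IL12A, -0.59 for CKMT1A and -0.62 for CCNJ.

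Among further genes fixed before the data were examined, the nuclear noncoding RNA NEAT1 rose by 0.62 (SE 0.08, limma adjusted p = 0.0251). MALAT1, another abundant nuclear noncoding RNA, had a difference of 0.30 (SE 0.08), which did not pass (limma adjusted p = 0.071). It passed in 4 of 19 alternatives, among them the mean of its probes (0.49, limma adjusted p = 0.0307). CA9 passed in only 9 of the 19, since no gene passed with an array or pair left out or with dim probes kept. MALAT1 did not pass with quantile normalization (0.11) or spike-in scaling (0.07). The probe used was the lowest of its 8 probes (0.30 to 0.61). NEAT1 was 1.05 with the mean of its probes and 0.40 with spike-in scaling, and passed with both. HIF1A mRNA fell by 0.81 (SE 0.15, limma adjusted p = 0.037). The transcription factor genes IRF4, on which myeloma cells depend, and KLF2 fell by 1.06 (SE 0.10, limma adjusted p = 0.0236) and 0.56 (SE 0.08, limma adjusted p = 0.0279). Several genes were well above background on all 3 hypoxia arrays and on no normoxia array, so only a lower bound of the fold can be given, taken against the dimmest signals above background. ADAM2 was at least 6.09-fold, C7orf57 at least 5.35-fold, DIRC3 at least 5.03-fold, ABCC13 at least 4.96-fold and SH3YL1 at least 3.59-fold higher, with limma adjusted p of 0.0236 for the first 4 and 0.0244 for SH3YL1. They were taken from 12 such genes, against 182 genes seen on all 3 normoxia arrays only, where more probes were above background. Of the 5 of those 182 taken by the naming rule, MARS2 (at least 2.36-fold lower in hypoxia, limma adjusted p = 0.0236) and SLEAR (limma adjusted p = 0.0247) passed, while ATP10A (2.23-fold, 0.158), TAS2R40 (2.18-fold, 0.095) and GUCA1ANB-GUCA1A (1.93-fold, 0.167) did not.

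Over all 31771 genes tested, 7544 passed limma's threshold, 3199 of them higher and 4345 lower in hypoxia, and 929 and 571 of these also differed at least 2-fold. The direction split depended on the scaling. With the arrays scaled to the spike-in controls, an alternative chosen after the data were seen, the median of all genes moved by a further -0.23 and 2017 genes were higher against 9513 lower, and with normexp background correction, likewise chosen afterwards, the split was 8267 against 5888. When any 1 of the 6 arrays was left out, untransduced, Scr or shKDM3A and at either oxygen level, 0 genes passed limma's threshold, with 8234 to 11319 at an unadjusted p under 0.05. Leaving out a construct pair is the same hypoxia fit as leaving out 1 of its arrays, so the 3 pairs add no further check. When dim probes were kept 0 genes passed as well, with 13218 at that unadjusted p. All hypoxia arrays lay in the other slide row from the normoxia arrays, so slide row and oxygen cannot be told apart. Each construct likewise filled 1 slide column, so column and construct cannot be told apart in the comparisons below.

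HIF target genes rose as a list, which had 51 members, 21 of them also held by another list, and 48 of them tested. Of the 48, 37 rose and 1 fell, with a median difference of 1.39 (camera adjusted p = 1.86e-16, and adjusted p = 0.619 with an estimated correlation), and adjusted over the list alone 39 were higher and 3 lower. HILPDA, a lipid droplet protein gene, rose by 3.14 and PFKFB4, a regulator of glycolysis, by 2.74, while RIOX2, a JmjC-domain ribosomal oxygenase gene that is also a MYC target, fell by 0.87. Of 28 genes of glycolysis and lactate export, 19 rose and 0 fell (median 0.65, camera adjusted p = 2.37e-09, and adjusted p = 0.39 with an estimated correlation). Adjusted over the list alone, 22 were higher and 2 lower. The lactate exporter gene SLC16A3 rose by 1.75, the glucose transporter gene SLC2A1 by 1.70 and PFKFB3 by 2.22. Of 21 genes of collagen modification and extracellular matrix, 10 rose and 0 fell (median 0.33, camera adjusted p = 6.74e-05, and adjusted p = 0.39 with an estimated correlation), and adjusted over the list alone 11 were higher and 1 lower. The collagen prolyl hydroxylase genes P4HA1 (1.99) and P4HA2 (1.89) and the lysyl hydroxylase gene PLOD2 (1.55) were among them. These 3 medians stayed above 0 under every scaling tried. The 50 cytosolic ribosomal protein genes had a median of 0.14 and passed camera as higher (adjusted p = 6.21e-05, and adjusted p = 0.39 with an estimated correlation), but 0 of them passed singly or adjusted over the list alone, and the median was -0.08 with spike-in scaling. The list did not pass with normexp (adjusted p = 0.416), quantile normalization (adjusted p = 0.141) or spike-in scaling (adjusted p = 0.542).

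Camera passed 8 lists as lower in hypoxia. Of 30 genes of ribosome biogenesis and MYC targets, 25 fell and 0 rose (median -0.71, camera adjusted p = 2.56e-10, and adjusted p = 0.619 with an estimated correlation), with UTP20 at -1.39, RRP9 at -1.37 and the spermidine synthase gene SRM at -1.30. Of 56 oxidative phosphorylation genes, 31 fell and 0 rose (median -0.54, camera adjusted p = 2.67e-09), including ATP5MC1 (-1.15) and NDUFS6 (-1.06), and of 22 tricarboxylic acid cycle genes 12 fell, including SDHB (-0.83), while IDH2 rose by 0.74 (median -0.45, camera adjusted p = 0.00941). Of 41 cell cycle genes, 20 fell and 0 rose (median -0.66, camera adjusted p = 4.35e-06), among them UBE2C (-1.51) and CDC20 (-1.48), and 13 of 19 replication-dependent histone genes fell (median -0.67, camera adjusted p = 2.21e-05), with H2AC11 at -1.20. Of 25 genes of the unfolded protein response, 17 fell, including the chaperone genes HSPA5 (-1.26) and SDF2L1 (-1.65), and PDIA3, a protein disulfide isomerase gene, rose by 0.43 (median -0.62, camera adjusted p = 2.21e-05). Of 30 plasma cell and myeloma genes, 12 fell, among them XBP1 (-0.99) and POU2AF1 (-1.05), and FGFR3 and the chemokine receptor gene CXCR4 (0.85) rose (median -0.43, camera adjusted p = 0.0326). Of 28 sterol synthesis genes, 12 fell, including DHCR7 (-0.91) and SQLE (-0.88), whereas INSIG2 (1.40), a negative regulator of the pathway, and the desaturase gene SCD (0.56) rose (median -0.45, camera adjusted p = 0.00402). Adjusted p with an estimated correlation was 0.697 for each of these lists but the first. Adjusted over the list alone, the lower genes numbered 28 for ribosome biogenesis, 40 for oxidative phosphorylation, 14 (and 2 higher) for the tricarboxylic acid cycle, 25 for the cell cycle, 15 for histones, 19 (2 higher) for the unfolded protein response, 15 (3 higher) for plasma cell genes and 16 (3 higher) for sterol synthesis. The 8 medians stayed below 0 under every scaling tried. With quantile normalization the tricarboxylic acid cycle (adjusted p = 0.0784) and plasma cell lists (adjusted p = 0.13) did not pass, and the plasma cell list also failed with spike-in scaling (adjusted p = 0.105) and without either shKDM3A array (adjusted p = 0.0617). In all, 12 of 27 lists passed camera with the preset correlation, 7 passed fry and 0 passed camera with an estimated correlation. The last count says little, since that test rests on 2 residual degrees of freedom. Ribosomal proteins, with an estimated correlation of only -0.004, went from an unadjusted camera p of 1.84e-05 to 0.0347.

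**Figure D2:**
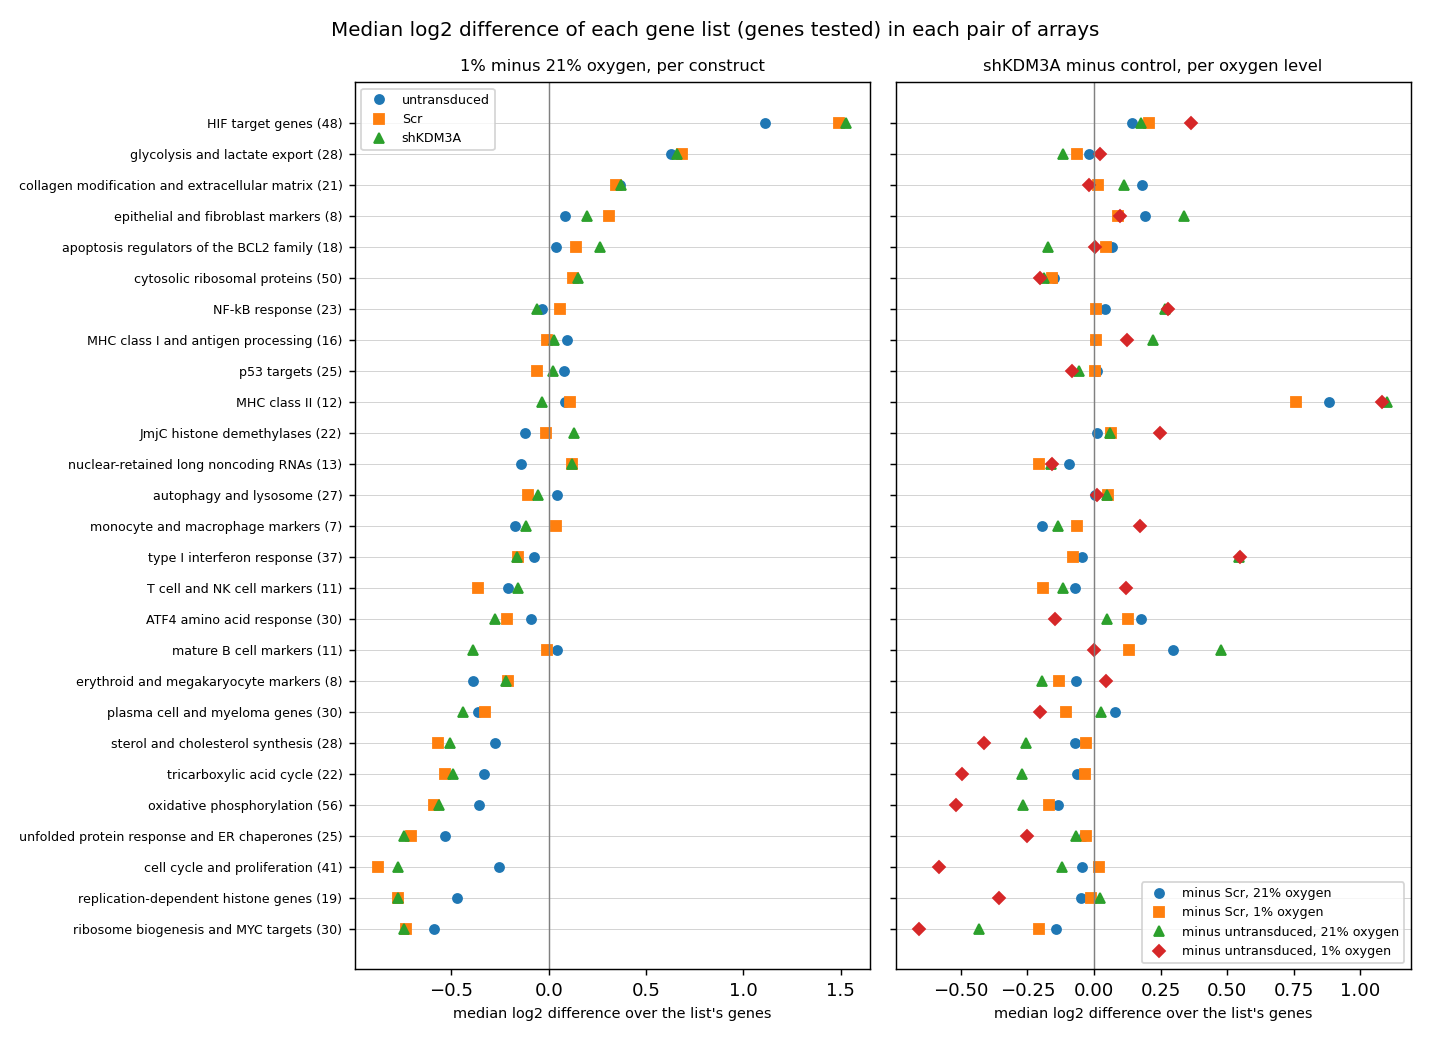
Median log2 difference (horizontal axes) of the genes of each of 27 lists, with the number of genes tested in parentheses; the left panel shows 1% minus 21% oxygen in each kind of cells and the right panel shows shKDM3A minus each control at each oxygen level, with 1 pair of arrays per point. HIF targets had hypoxia medians of 1.11, 1.49 and 1.53, and MHC class II genes had shKDM3A medians between 0.758 and 1.101 in the 4 pairs.

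The second comparison asked which genes differ when KDM3A is knocked down, as shKDM3A minus Scr cells. No gene passed limma's adjusted threshold (0 of 31771, smallest adjusted p 0.466), with 2937 at an unadjusted p under 0.05 where chance gives 1589. With the trended, robust spread 117 genes passed, 85 higher and 32 lower, with normexp background correction 170 passed, and against untransduced cells 562 passed. Against the mean of both controls 0 passed (smallest limma adjusted p 0.149), with 6188 at an unadjusted p under 0.05. In simulated arrays of the 31771 genes with 200 changed ones, the comparison with Scr called 0% of genes changed by 1 and 0% of genes changed by 2 on the log2 scale, while with 6000 changed genes it called 74.0% and 91.2%. The 20 genes below were taken by size and by a like direction against both controls at both oxygen levels, and 13 of them passed with the trended, robust spread.

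Genes of antigen presentation stood among those with higher values in shKDM3A cells. HLA-DQA1 differed by 1.02 (SE 0.15) and HLA-DRB5 by 1.07 (SE 0.13) from Scr. The serine protease inhibitor gene SPINK2 differed by 1.26 (SE 0.13), the neutrophil protease gene CTSG by 1.38 (SE 0.23), the trefoil factor gene TFF2 by 1.19 (SE 0.15), ARHGEF40 by 1.57 (SE 0.24), NSG2 by 1.52 (SE 0.28) and DPYSL3 by 1.04 (SE 0.11). These 8 passed with the trended, robust spread (adjusted p 0.00879 to 0.0338), while GPR162 (1.19) and LARP6 (1.01) did not. Lower values were found for LHFPL6 (-2.34, SE 0.32), the spindle checkpoint gene MAD2L1 (-0.94, SE 0.20), TAF5L (-0.88, SE 0.09) and PDE4DIP (-1.11, SE 0.13), which passed with that spread as KDM3A did (adjusted p 0.00879 to 0.0442). The growth factor gene IGF2 (-1.26, SE 0.12), the nuclear receptor gene ESRRG (-1.18, SE 0.11), the fatty acid receptor gene FFAR2 (-1.16, SE 0.11), HBBP1 (-1.22, SE 0.48) and SLC28A1 (-1.74, SE 0.39) did not pass with it (adjusted p 0.0576 to 0.206). Probes disagreed for SLC28A1 (-1.74 and 0.10), TAF5L (-0.88 and -0.21) and PDE4DIP (-1.11 to 0.17), which were -0.82, -0.54 and -0.34 with the mean of their probes. With normexp 7 of the 20 genes shrank by over 1.5 times, to 0.90 for ARHGEF40, 0.52 for LARP6, -0.96 for LHFPL6, -0.41 for IGF2, -0.49 for ESRRG, -0.50 for FFAR2 and -0.87 for SLC28A1. HBBP1 was -0.63 without the shKDM3A hypoxia array. MALAT1 differed by -0.15 (SE 0.10, limma adjusted p = 0.664) and by 0.003 with quantile normalization. Its 8 probes gave -0.47 to -0.10. KLF2 differed by 0.70 (SE 0.10, limma adjusted p = 0.466). It passed in 2 of 16 alternatives, normexp (limma adjusted p = 0.00986) and the trended, robust spread. These were the only 2 of the 16 in which any gene passed. IRF4 differed by 0.12 (SE 0.12), NEAT1 by 0.14 (SE 0.09) and HIF1A by -0.16 (SE 0.18). With an array left out IRF4 ranged from -0.00034 to 0.24 and HIF1A from -0.33 to -0.001, and NEAT1 was 0.25 with quantile normalization, none of them passing. TAFA2 was seen on both shKDM3A arrays and on none of the 4 control arrays (at least 2.59-fold higher), as were VSTM2A-OT1 (2.53-fold), BPIFC (2.08-fold), ZNF503-AS2 (2.03-fold) and LINC01625 (1.85-fold), from 28 such genes. Seen on all 4 control arrays and on no shKDM3A array were 5 genes, namely KRT16P2 (1.85-fold), ADAMTS17 (1.82-fold), GYG2 (1.65-fold), RHOBTB1 (1.60-fold) and TSC22D1-AS1 (1.48-fold). The 2 rules ask for unlike numbers of arrays, so the counts of 28 and 5 are not comparable. None of these 10 named genes passed the adjusted limma threshold.

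The MHC class II list covers the presentation of antigen to helper T cells and includes CD74 and the transactivator gene CIITA. All 12 of its genes had higher values in shKDM3A than in Scr cells over both oxygen levels (median 0.82, camera adjusted p = 5.93e-14, and adjusted p = 0.773 with an estimated correlation). No member passed over all genes, 9 were higher adjusted over the list alone, and 9 passed with the trended, robust spread. HLA-DOA differed by 1.79 (SE 0.24), HLA-DRA by 1.05 (SE 0.12) and HLA-DPA1 by 1.03 (SE 0.10), and the smallest difference was that of HLA-DOB at 0.02, which in hypoxia alone was -0.07. Against untransduced cells 7 of the 12 passed, all higher. HIF targets had a median of 0.19 with 34 of 48 higher (camera adjusted p = 3.28e-05, and adjusted p = 0.773 with an estimated correlation), and 24 of 30 genes of the ATF4 amino acid response were higher (median 0.17, camera adjusted p = 0.000165, and adjusted p = 0.773 with an estimated correlation). Against untransduced cells the ATF4 list had a median of -0.04. All 50 ribosomal protein genes were lower, by a median of -0.15 (camera adjusted p = 3.56e-07, and adjusted p = 0.567 with an estimated correlation), which was -0.01 with quantile normalization, and they were the 1 list that passed fry (adjusted p = 0.0029). Ribosome biogenesis genes (29 of 30 lower, median -0.16, camera adjusted p = 0.000984) and oxidative phosphorylation genes (52 of 56 lower, median -0.14, camera adjusted p = 0.00108) passed as lower, each with an adjusted p of 0.773 with an estimated correlation. Only 1 lower list instead of 3 passed with quantile normalization, which left ribosome biogenesis, and without the Scr normoxia or the shKDM3A hypoxia array, which left ribosomal proteins. The adjusted p for ribosomal proteins was 0.672 and for oxidative phosphorylation 0.0796 with quantile normalization. HIF targets did not pass without the shKDM3A hypoxia array (adjusted p = 0.0566), nor the ATF4 list without the shKDM3A normoxia array (adjusted p = 0.0984). Adjusted over the list alone, limma passed no gene of these 5 lists other than KDM3A, which is a HIF target. With normexp 11 lists passed camera and against untransduced cells 10. The other 21 lists did not pass, collagen modification and extracellular matrix being nearest (adjusted p = 0.055). That list passed as higher with the mean of a gene's probes (adjusted p = 0.0332), the strict filter (adjusted p = 0.0317), normexp (adjusted p = 0.00819) and without either untransduced array, the Scr hypoxia or the shKDM3A hypoxia array. The cell cycle list, with a median of -0.01 and a test in the upward direction, was among them (adjusted p = 0.623), but passed as higher without the Scr normoxia array (adjusted p = 0.0158). Further lists gained a call as higher, namely BCL2 family, autophagy and lysosome, MHC class I and p53 lists with normexp, mature B cell markers with the strict filter, and epithelial and fibroblast markers without the Scr hypoxia array.

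**Figure D3:**
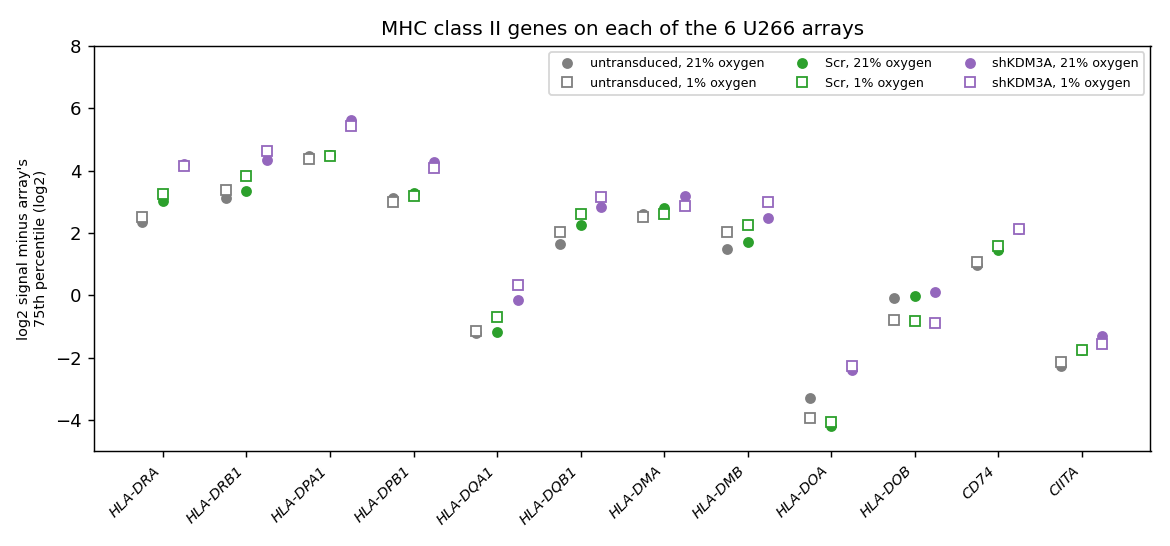
Normalized log2 signal (log2 signal minus the array's 75th percentile, vertical axis) of 12 MHC class II genes, with 1 array per point, colours for the kind of cells, filled circles for 21% and open squares for 1% oxygen. HLA-DRA lay at 4.22 and 4.16 in shKDM3A cells and at 3.01 and 3.26 in Scr cells, while HLA-DOB differed little between the kinds of cells.

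The third comparison set Scr against untransduced cells, as the effect of transduction and of separate culture. Interferon-stimulated genes were higher in Scr cells. IFI44L rose by 3.09 (SE 0.23, limma adjusted p = 0.0405), IFI44 by 2.22 (SE 0.11, limma adjusted p = 0.0355) and MX1 by 1.07 (SE 0.09, limma adjusted p = 0.0432), and 33 of 37 type I interferon genes had higher values (median 0.58, camera adjusted p = 3.86e-09, and adjusted p = 0.47 with an estimated correlation). Adjusted over the list alone 21 were higher and 1 lower. SH3RF1 (2.73, SE 0.17) and the inhibitory receptor gene CD300A (2.59, SE 0.18) rose, and ASTN1 (-4.24, SE 0.15), FAM3B (-3.97, SE 0.18) and PDZRN4 (-3.86, SE 0.09) fell. The apoptosis genes PMAIP1 (2.31) and BMF (1.67) and the lymphotoxin gene LTB (2.18) rose as well. In all, 407 genes passed limma's threshold, 170 higher and 237 lower. With spike-in scaling, which moved the median of all genes from 0.01 to 0.18, 240 were higher and 171 lower. Without any 1 of the 6 arrays 0 genes passed, with 3238 to 6371 at an unadjusted p under 0.05, and with dim probes kept 0 passed, with 6226. With normexp 3924 passed, and with probes above background on every array 1804. Camera passed 9 lists, of which NF-kB response (median 0.22, adjusted p = 0.0356) and MHC class II (median 0.23, adjusted p = 0.00651) were also higher, with 6 higher and 3 lower NF-kB genes and 3 higher class II genes adjusted over the list alone. Cell cycle (median -0.36, adjusted p = 1.57e-07), ribosome biogenesis (-0.37, 5.98e-08), oxidative phosphorylation (-0.23, 5.98e-08), tricarboxylic acid cycle (-0.30, 0.00181), sterol synthesis (-0.25, 0.000644) and ATF4 genes (-0.19, 0.00651) were lower. Each of these 8 had an adjusted p of 0.816 with an estimated correlation. No member of the lower lists passed over all genes, and adjusted over the list alone 3 ATF4 genes and 1 sterol synthesis gene were lower. These 9 medians kept their sign under the 4 scalings. The medians of the 6 lower lists were larger in the hypoxia pair than in the normoxia pair, most of all for the cell cycle (-0.59 against -0.15) and oxidative phosphorylation (-0.37 against -0.14), so the pooled sizes of these 2 lists rest mostly on 1 pair of arrays.

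The fourth comparison asked whether hypoxia acts differently in shKDM3A cells than in controls. No gene passed the interaction test (0 of 31771, smallest adjusted limma p 0.452), with 2537 at an unadjusted p under 0.05 against 1589 by chance, and with normexp 101 passed. The test left 1 residual degree of freedom, and in simulated arrays it called 0% of 6000 genes whose response was changed by 1 or 2. The naming rule took genes with a symbol and above background on every array, by the smaller difference from the 2 control responses. Their differences of response were 2.14 for PP2D1, 1.95 for ITGBL1, 1.92 for TMPRSS7, 1.76 for OR56B4 and 1.68 for GAL3ST4, and -3.04 for QNG1, -2.84 for LINC00544, -2.61 for SLC22A11, -2.57 for OR6K2 and -2.38 for OR2L1P. None of them passed. The probes for QNG1 disagreed on the knockdown (0.08 and 1.51), as did those for LINC00544 (-0.82 to 0.25). The hypoxia responses of all genes seen on every array correlated across 25721 genes, which are not independent replicates, with Pearson's r of 0.778 between untransduced and Scr cells, 0.700 between untransduced and shKDM3A cells and 0.790 between Scr and shKDM3A cells.

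The design text of the study names genes raised by hypoxia and lowered by KDM3A knockdown. Among 25721 genes above background on every array, 575 were at least 2-fold higher in hypoxia in both controls, and 184 were at least 2-fold lower in shKDM3A than in both control cells in hypoxia. Only 4 genes met both conditions, where independent lists would share 4.11. Probes without a symbol stand for the others, and the one that could be named was SNAP91, a clathrin assembly gene of synapses, whose 2 probes disagreed on the knockdown (-1.57 and -0.16) and on hypoxia (0.67 and -0.15). KDM3A itself missed the threshold, since its difference from untransduced cells in hypoxia was -0.86. In 100 simulated draws of an unchanged knockdown array the overlap was 0.58 on average and at most 4, but the lowered list held only 13.6 genes on average there, against 184 in the data, so the draws give no count to hold the 4 against. The count changed with the size threshold, being 92 at 1.5-fold (63.3 for independent lists), and with the controls. It was 42 (14.5 for independent lists) with hypoxia taken from untransduced cells and the knockdown against Scr, and 59 (48.1 for independent lists) with the controls exchanged. With the Scr arrays for both it was 85 (18.7 for independent lists), and part of that excess may come from the shared array. Without the Scr hypoxia array, which leaves the untransduced arrays for both, it was 123. Leaving out the untransduced hypoxia array is the same count as the Scr arrays for both (85). Without the untransduced normoxia array it was 24 and without the Scr normoxia array 30. At the main threshold 9 genes were raised by hypoxia and also at least 2-fold higher in shKDM3A cells, against 1.45 for independent lists. This opposite combination also exceeded independent lists with hypoxia from untransduced cells and the knockdown against Scr (22 against 4.35), so the excess was not specific to lowering. With the controls exchanged it was 255 against 31.9, but the difference from untransduced cells also holds the effect of transduction.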

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

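The interaction test was planned, and the opposite directions below were looked for only after the data were seen, among the named genes. In each, the single shKDM3A pair of arrays moved one way between normoxia and hypoxia and both control pairs moved the other way. TMPRSS7, GAL3ST4, LINC00544, SLC22A11, OR6K2 and OR2L1P were named for a shKDM3A response far from both control responses. SNAP91 was named for a rise in both controls and a low shKDM3A value in hypoxia. Their opposite directions therefore largely restate the naming rules, and opposite directions were not counted over all genes. The interaction test passed for none of them, with adjusted limma p of 0.452 to 0.732, and each rests on 1 shKDM3A pair.

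The hypoxia response in shKDM3A cells was 1.51 for TMPRSS7, against -0.56 in untransduced and -0.25 in Scr cells, and 0.96 for GAL3ST4, against -0.79 and -0.65. For LHFPL6, the gene with the lowest knockdown value among those named, it was 0.26 against -0.84 and -0.65. The LHFPL6 signal in shKDM3A cells was dim (-5.15 in normoxia and -4.89 in hypoxia), so a fall like that of the controls may be hidden near background. For FAM3B, a secreted cytokine-like protein gene, the response was 0.088 against -0.46 and -0.35. It was lower in shKDM3A cells for the noncoding RNA LINC00544, with -1.66 against 1.42 and 0.96 by 1 of its 4 probes, which disagreed on hypoxia (-0.53 to 1.26), and for the urate transporter gene SLC22A11, with -1.69 against 0.30 and 1.54. The olfactory receptor pseudogene OR2L1P had -1.58 against 1.19 and 0.39, and the olfactory receptor gene OR6K2 had -1.51 against 1.70 and 0.42. SNAP91 had -0.56 against 1.41 and 1.15 by 1 of its 2 probes, which disagreed on hypoxia (0.67 and -0.15).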

How the results depend on the processing

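Normexp background correction and spike-in scaling were chosen after the data were seen, and the other alternatives before. KDM3A stayed lower in shKDM3A cells under every alternative run, by -0.86 (against untransduced) to -1.29. Quantile and bright-probe scaling, the mean of a gene's probes and the deposited log2 table kept the total counts of genes and lists within 1.5 times, but with quantile normalization 1 lower list instead of 3 passed in the knockdown, as without the Scr normoxia or the shKDM3A hypoxia array. Leaving out an array gave 0 genes for hypoxia and for the vector, since 1 residual degree of freedom remains, as did leaving out a construct pair for hypoxia. It gave 4 to 123 for the overlap and 4 to 8 lists in the knockdown. The interaction has no test with an array left out, and the overlap no value without the shKDM3A hypoxia array. For hypoxia, a left-out construct pair is the same fit as 1 left-out array of that construct. Slide as a block was not run, since there is 1 slide.

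With normexp on the median signal, counts were 14155 genes for hypoxia, 170 for the knockdown, 3924 for the vector, 101 for the interaction, 0 for the overlap and 11 lists in the knockdown. With spike-in scaling they were 11530 for hypoxia and 2 for the overlap. With dim probes kept, they were 0 for hypoxia, 0 for the vector and 117 for the overlap, and with the strict filter 1804 for the vector. Without construct in the model 2149 genes passed for hypoxia, and with the trended, robust spread 12192, and 117 for the knockdown. Against untransduced cells the knockdown gave 562 genes and 10 lists. The overlap was 92 at 1.5-fold, 42 and 59 with no array in common and 85 with Scr arrays for both. Lists numbered 0 in hypoxia and 0 in the knockdown with an estimated correlation, and 7 and 1 with fry. Normexp shrank 8 named genes in hypoxia and 7 in the knockdown by over 1.5 times. The sign turned for MALAT1 in the knockdown with quantile normalization (0.003) and for IRF4 without the shKDM3A normoxia array (-0.00034, the lowest of -0.00034 to 0.241 with an array left out). Apart from the left-out arrays, the cause was not tested. Dim probes limit detection most in hypoxia, where fewer were above background.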

Other observations

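Of the tests below, the one on the splits of the arrays and the one on HIF targets in normoxia were set before their results were seen, and the others afterwards. Beside the groups described, JmjC histone demethylase genes did not move as one list in hypoxia (camera adjusted p = 0.262), but 7 of 22 rose and 2 fell. KDM5B rose by 1.86, KDM6B by 1.84 and KDM7A by 1.43 besides KDM3A, and the oxygenase genes RIOX2 (-0.87) and RIOX1 (-0.60) fell. Of 18 BCL2 family regulators, 6 rose, among them BBC3 (1.67), BNIP3L (1.59) and BMF (1.34), all of which promote cell death or mitophagy, and BAK1 (-0.63) and BID (-0.41) fell (camera adjusted p = 0.101). Among 13 long noncoding RNAs, H19 rose by 1.28 and DANCR (-1.09), SNHG12 (-0.71) and SNHG1 (-0.66) fell (camera adjusted p = 0.78). The B lineage kinase gene BLK rose by 2.26 and SPIB by 0.94, while CD79B fell by 0.81, within a list of 11 mature B cell markers that did not pass (camera adjusted p = 0.78). Interferon genes (camera adjusted p = 0.416), NF-kB genes (0.467), p53 targets (0.78), autophagy and lysosome genes (0.411), the ATF4 response (0.411), MHC class I (0.776) and class II (0.467) did not pass in hypoxia, nor did markers of T and NK cells (0.905), monocytes (0.879), epithelium and fibroblasts (0.303) and erythroid cells (0.303). The call depended on the setting for 4 of these lists. Autophagy and lysosome (adjusted p = 0.00998) and BCL2 family genes (adjusted p = 0.0497) passed as higher with quantile normalization, ATF4 genes (adjusted p = 0.00696) and interferon genes (adjusted p = 0.0191) as lower with normexp, and interferon genes also passed fry as lower (adjusted p = 0.014). Adjusted over the list alone, 7 JmjC genes were higher and 3 lower, 6 and 3 BCL2 family genes, 6 and 6 noncoding RNAs and 3 and 2 mature B cell markers. The median and the tested direction differed in sign for the mature B cell markers (-0.27) and for autophagy and lysosome genes (-0.01), and the medians of the JmjC, BCL2 family, NF-kB, p53, MHC class I and class II, and epithelial lists, which were above 0, lay under 0 with spike-in scaling.

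Untransduced cells stood apart from both transduced kinds. Among 25721 genes seen on every array, 412 were at least 2-fold away from both other constructs at both oxygen levels in untransduced cells, against 5 in Scr and 12 in shKDM3A cells. The difference of shKDM3A from untransduced cells correlated across genes between normoxia and hypoxia with Pearson's r of 0.662, and that from Scr cells with 0.323; genes are not independent replicates. The 75th percentile relative to the spike-in controls was lower in hypoxia by -0.23 on average, and in all 3 constructs.

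For hypoxia, the 6 arrays can be split into 3 and 3 in only 10 ways, too few for a share under 0.05. The real split gave 7544 genes and the highest of the others 0. The 1 of the 10 as large as the real one is the real split itself. Every other split mixes the oxygen levels and leaves the oxygen difference in the residual spread of the fit. Their 0 therefore says nothing on how many genes pass by chance, and no conclusion is drawn from it.

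The MHC class II genes had higher values in shKDM3A cells. Scaling is argued against by quantile normalization, the 1 scaling that does not shift all genes of an array alike, in which the list's median exceeded that of all genes by 0.85, and monocytes or macrophages among the cells are argued against by their markers, whose 75th percentile was -0.077 and of which CD14 lay at -1.55 and -2.36 in shKDM3A cells. Mature B cells stay open, with a 75th percentile of 0.28 in which BLK (0.72) was higher and CD79B (-0.40) lower, and so does cross-hybridization between class II copies, since CD74 differed by 6.29 standard errors but CIITA, the class II transactivator gene, by only 2.55. Drift between separately grown cultures cannot be told apart from the knockdown, because 1 hairpin and 1 culture per oxygen level were used and the list's median also differed by 0.23 between Scr and untransduced cells. Nor can slide column, since each construct filled 1 column. An effect of KDM3A loss on class II expression may be a hypothesis for a second hairpin.

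HIF targets, KDM3A among them, had a list median of 0.19 above Scr in shKDM3A cells, with 34 of 48 higher and 0 past the threshold. Camera passed the list with the preset correlation, while 0 of 27 lists passed with an estimated one (adjusted p = 0.773 for this list). Fry did not pass it (adjusted p = 0.473), nor did camera without the shKDM3A hypoxia array. Deeper hypoxia in that culture stays open. The list's median difference from Scr was 0.14 in normoxia and 0.21 in hypoxia, which met the rule set beforehand for arguing against it. Against untransduced cells, however, the medians were 0.18 and 0.36. In the normoxia pair with Scr the ATF4 list (0.18) and the collagen and matrix list (0.18) moved as much, so 1 such pair cannot decide. A scaling artifact is argued against by a list median 0.25 above that of all genes with quantile normalization, and a low reading of the Scr arrays by a median of 0.27 against untransduced cells. Culture drift and slide column were not tested, and a raised HIF target level at both oxygen levels remains a hypothesis that may not hold in repeated cultures.

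The overlap of genes raised by hypoxia and lowered by the knockdown may draw on error of the Scr and the untransduced hypoxia arrays, each of which enters both comparisons. The count was 85 with the Scr arrays for both comparisons and 123 with the untransduced arrays for both. With no array in common it was 42 with hypoxia from untransduced cells (Fisher's exact test against 14.5 for independent lists, one-sided p = 8.54e-10) and 59 with the controls exchanged (one-sided Fisher's exact p = 0.0616 against 48.1). These p-values treat genes as independent, which they are not, and measure no variation between cultures. Genes raised by hypoxia and higher in shKDM3A cells were also in excess with hypoxia from untransduced cells and the knockdown against Scr (22 against 4.35), so the excess was not specific to lowering. With the controls exchanged they numbered 255 against 31.9, but there the difference from untransduced cells also holds the effect of transduction. The p-values assume independent genes, and of the settings with no array in common 1 passed and the other did not. Shared error and a true overlap therefore cannot be told apart with 1 array per group.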
